A study of Mus musculus with 4 samples.

How the data were processed

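Gene expression was measured in alveolar macrophages, the resident macrophages of the airspaces of the lung, that were sorted by flow cytometry from adult mice on a C57BL/6 background. One genotype carried floxed alleles of Pparg alone and is called WT. The other also carried a Cre recombinase driven by the CD11c promoter and is called KO. Per the labels, each genotype had 2 biological replicates, and each replicate was a pool of cells from 2 mice hybridised to its own Affymetrix array, which gave 4 arrays in 2 groups. Per the labels' protocols, lung tissue was digested with collagenase and DNase, and viable CD45-positive, CD11c-high, autofluorescent, Siglec-F-positive cells were sorted. The protocol took CD11b-low cells from WT mice and CD11b-high cells from KO mice, so the genes of these surface proteins describe the gate.

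The deposited values were log2 expression values per probe set, made with RMA in R 2.15.2 per the submitters' processing notes. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a probe set. The genome build and the settings of RMA are not given in the sources used here, and no coordinates are printed. The table held 28371 probe sets with values from 0.96 to 12.11. Each array had a median of 3.14, and the sorted values of the arrays differed by at most 0.012, so the arrays share 1 distribution and a change that moved most transcripts one way would not be seen. Values near the bottom of the scale are compressed, which understates the fold change of a gene that was dim in one group.

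Probe sets were named from the platform's annotation. Of these, 21158 had 1 gene symbol, 1881 had several and 5332 had none listed there. The Entrez identifiers of 21128 single-gene probe sets were found in the reference gene table, and 0 symbols changed on update. Probe sets with several genes or none were left out of the comparison by gene. For 1368 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was used. This left 18782 genes, with no filter on intensity.

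KO and WT were compared with limma 3.58.1 in R 4.3.3, by a linear model on the log2 values with the group as its only term and empirical Bayes moderation of the variance, two-sided. The fit had 2 residual degrees of freedom and 4.16 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene counted as changed when its adjusted p was under 0.05. Differences are KO minus WT on the log2 scale with the standard error (SE) of the model, and levels are means with the standard deviation (SD) over arrays. The number of arrays limits the precision of every value.

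Before the data were examined, 38 gene lists were written from general knowledge of macrophages, lipid metabolism, inflammation, growth and the cells of the lung. They held 732 genes, of which 656 were measured and 76 were not analysed here, 29 of these because they lay on probe sets with several gene names. For each list the members higher, lower and not past the test were counted, adjusted over all genes and adjusted over the list alone. For 34 lists a shift against all other genes was tested with camera (limma) at a preset correlation between genes of 0.01 and adjusted over those lists. The shift was also tested with a correlation estimated from the residuals, and with fry, which tests whether the members of a list move without comparing them with other genes. The remaining lists held the targeted gene, the sort gate, the sex-linked genes and the genes of cell stress and dissociation, and were counted only. Lists share members, and counts of different lists are not independent.

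Genes named were fixed by a rule before the data were examined. They are Pparg and the sort gate genes, the 12 genes with the largest increase and the 12 with the largest decrease among those past the test whose KO arrays both lay beyond both WT arrays, and up to 4 members with the smallest p of each list described, or up to 2 where no member passed. Predicted genes, microRNAs and probe sets with several genes were passed over. Other genes were chosen after their values were seen, among them members named to complete a direction of 5 or fewer genes in a list.

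The procedure was tested on simulated data with 18782 genes, 4 arrays and the spread of the real arrays. For the comparison of KO with WT, 2 of 67 genes changed by 0.5 on the log2 scale were called, 53 of 67 changed by 1 and 64 of 66 changed by 2, with 5 unchanged genes called. In the simulation 0 of 38 lists without a shift were called. Only these genes and a shifted list were changed, a far smaller share than the 14.3% of genes called in the real data. The adjustment is stricter where fewer genes change, so these rates of recovery do not carry over to the real arrays. Its genes were drawn independently of each other, so it does not test list calls where the genes of a list vary together.

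The alternatives were quantile normalization of the values again, a shift of the arrays to 1 median, an intensity trend or robust moderation in limma, a filter leaving out genes whose mean lay under the 40th percentile of all probe sets (2.59 on the log2 scale), the replicate number as a block, array weights, the mean of a gene's probe sets, all probe sets with or without a name, leaving out each array in turn, limma's treat test against a difference of 0.5, and an ordinary 2-sample test without moderation. The shifts were also computed on ranks. When 1 array is left out, its group has a single array, which is assumed to vary like the other group.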

Results

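The series compared alveolar macrophages of 2 groups of adult mice. KO mice carried floxed Pparg alleles and a Cre driven by the CD11c promoter, designed to delete Pparg. WT mice carried the floxed alleles without Cre. Pparg encodes the nuclear receptor PPARγ, a lipid-sensing transcription factor. The question, as the series title states it, is what PPARγ controls in the identity of these cells. There were 2 WT and 2 KO arrays, each from sorted cells pooled from 2 mice. Across genes, the WT arrays correlated with r = 0.995 and the KO arrays with r = 0.996, while pairs of different genotype lay between 0.974 and 0.980. The first principal component, which separated the genotypes, held 87.1% of the variance.

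The targeted gene, Pparg, measured 9.72 ± 0.05 (SD, n = 2) in WT and 9.66 ± 0.10 (SD, n = 2) in KO on the log2 scale, a difference of -0.06 ± 0.10 (SE; limma adjusted p = 0.79). Where the probes of its probe set lie relative to the deleted part is not known here, so this level does not check the genotype of either group. Directions below are those between arrays labelled KO and arrays labelled WT. Of the genes behind the sort gate, Itgam, which encodes CD11b, was higher in KO by 5.76 ± 0.14 (SE; adjusted p = 1.25e-05), as the gates of the groups were set. Siglecf was lower by -3.27 ± 0.17 (adjusted p = 1.64e-04) although both groups were gated as Siglec-F-positive. Ptprc, which encodes CD45, differed by -0.52 ± 0.10 (adjusted p = 0.0212), with adjusted p = 0.117 without KO replicate 1, 0.0769 without KO replicate 2 and 0.0982 without WT replicate 1. Itgax, which encodes CD11c, differed by 0.24 ± 0.09 (adjusted p = 0.168), and the macrophage marker gene Adgre1 by 0.07 ± 0.11 (adjusted p = 0.751).

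Thbs1, which encodes the matrix glycoprotein thrombospondin 1, rose in KO macrophages by 7.04 ± 0.34 (SE) from 3.36 ± 0.80 (SD, n = 2) to 10.4 ± 0.11 (SD, n = 2). The next largest increases were in C1qb, a chain of complement C1q (6.48 ± 0.34), the heparan sulfate-cleaving enzyme gene Hpse (6.30 ± 0.10) and the macrophage elastase gene Mmp12 (6.11 ± 0.12). The largest decreases were in the keratin gene Krt79 (-6.19 ± 0.50), the fatty acid-binding protein gene Fabp1 (-5.96 ± 0.18), the lipid droplet gene Cidec (-5.67 ± 0.10) and Cpne5 (-5.53 ± 0.30). Adjusted p-values of these 8 genes ran from 8.27e-06 to 7.86e-04.

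After Itgam, the other genes among the 12 highest were C3ar1 (5.52), the receptor for complement C3a, Fstl1 (5.40), the phospholipase gene Pla2g2d (5.23), Rnase2a (5.19), the aminopeptidase gene Anpep (5.19), Papss2 (5.16) and Mfge8 (5.14), which encodes a bridge to apoptotic cells. The other genes among the 12 lowest were Tc2n (-5.07), the keratin gene Krt19 (-4.93), the transporter gene Slco2b1 (-4.93), the galanin gene Gal (-4.82), the potassium channel gene Kcnk5 (-4.45), the adhesion molecule gene Epcam (-4.37), the serotonin receptor gene Htr2c (-4.32) and the lipase gene Lipf (-4.24). Over all 18782 genes, 1391 were higher and 1289 lower in KO, 14.3% of those tested. Of these, 584 and 397 differed by at least 1 on the log2 scale. Without KO replicate 1 the counts were 726 higher and 656 lower, and without KO replicate 2 they were 816 and 647. Without WT replicate 1 they were 938 and 809, and without WT replicate 2 they were 1227 and 1057. A test against a difference of 0.5 called 498 higher and 336 lower. An ordinary test without moderation called 0 after adjustment, with 3635 genes at an unadjusted p under 0.05 against 5006 with limma.

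**Figure D1:**
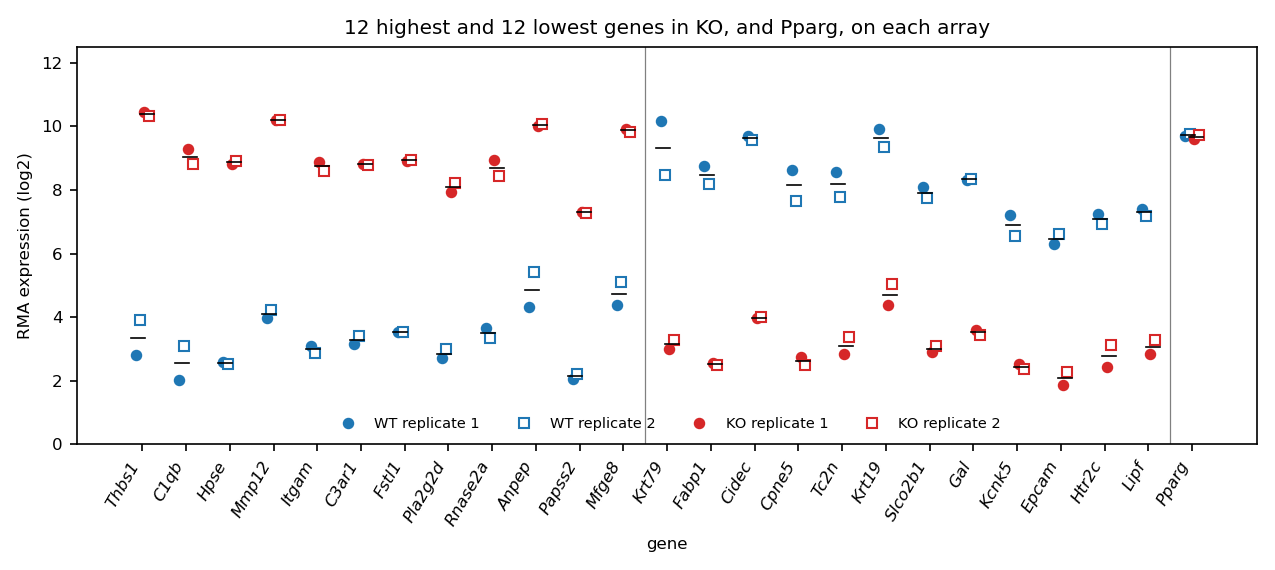
Expression (RMA, log2) of the 12 genes with the largest increase, the 12 with the largest decrease and Pparg, as 1 point per array with a line at each group's mean (n = 2 pools per group). The KO points of Thbs1 lie near 10.4 against 3.36 for the WT mean, those of Cidec near 3.98 against 9.65, and the 4 points of Pparg overlap.

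Genes typical of alveolar macrophages were lower in KO. Of 29 measured members of the alveolar macrophage signature, 16 were lower, 2 higher and 11 not past the test (21 lower and 4 higher when adjusted over the list alone), with a median difference of -0.85. Besides Cidec, Fabp1 and Epcam, Perp was lower by -2.59 ± 0.12 (adjusted p = 1.01e-04), while Ctsk, the gene of cathepsin K (0.83 ± 0.11), and the amino acid transporter gene Slc7a2 (0.46 ± 0.10) were higher, the count of higher genes being 1 when any 1 array was left out. Here and in the other lists, members beyond the 4 with the smallest p, named where 5 or fewer genes went one way, were chosen after their values were seen. The list shifted down against other genes (camera adjusted p = 5.90e-09; adjusted p = 0.423 with an estimated correlation). Not every typical gene passed the test. Car4 differed by -0.31 ± 0.10, with both KO arrays (10.15 each) below the WT arrays (10.43 and 10.5). Plet1 differed by -0.05 ± 0.09, Chil3 by 0.04 ± 0.10 and Atp6v0d2 by 0.00 ± 0.09. None of the 4 was past the test over all genes. Their WT means were 10.5 (Car4), 11.2 (Plet1), 11.1 (Chil3) and 10.8 (Atp6v0d2), near the top of the scale. Whether signal there understates a fall was not tested. These 4 genes and the next 2 were chosen after their values were seen. The scavenger receptor gene Marco differed by -2.62 ± 0.81 (adjusted p = 0.0897) and Fabp4 by -2.07 ± 0.68 (adjusted p = 0.109), with WT arrays far apart. Marco read 7.22 and 4.43 in WT replicates 1 and 2 against 3.04 and 3.37 in KO, and Fabp4 7.57 and 5.21 against 4.19 and 4.45. Without WT replicate 2, Marco differed by -4.01 and Fabp4 by -3.25, and without WT replicate 1 by -1.23 and -0.89. These fits hold a single WT array, so the spread between the WT arrays does not enter them. The count of lower signature genes was 16 when either WT array was left out and 13 when either KO array was left out.

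Of 24 genes of fatty acid oxidation, 14 were lower, 0 higher and 10 not past the test (16 lower and 1 higher when adjusted over the list alone), with a median of -0.52. The beta-oxidation enzyme genes Acaa1b (-3.81 ± 0.35), Hsd17b4 (-1.47 ± 0.13), Acaa1a (-1.33 ± 0.12) and Ehhadh (-1.17 ± 0.11) led the list. Camera gave an adjusted p of 2.98e-06 for its shift down (adjusted p = 0.423 with an estimated correlation). Of 26 known PPAR target genes, 6 of which are also in the alveolar macrophage signature, 11 were lower and 2 higher (13 and 2 when adjusted over the list alone), with a median of -0.40. Among those not past the test, Pck1 (2.32), Aqp7 (1.87) and Cidea (1.8) were too dim in WT to show a fall. Me1 (2.64), Adipoq (2.71), Plin5 (2.82), Plin1 (3.05) and Plin4 (3.12) also lay below the array median of 3.14 in WT. Others, such as Cd36 (10.2) and Scd1 (6.78), lay well above it. Angptl4, an inhibitor of lipoprotein lipase, fell by 2.18 ± 0.13, while the fatty acid transporter gene Slc27a1 (1.62 ± 0.13) and the sterol hydroxylase gene Cyp27a1 (1.10 ± 0.13) were higher. The list shifted down (camera adjusted p = 7.04e-04; adjusted p = 0.435 with an estimated correlation), and 7 of its genes were lower without KO replicate 1 and 7 without KO replicate 2. Of 24 genes of lipid droplets and triglyceride metabolism, 8 were lower and 1 higher (9 and 3 when adjusted over the list alone), among them Gpat3 (-1.19 ± 0.10) and the lipase inhibitor gene G0s2 (-0.98 ± 0.11) lower and Agpat2 (0.86 ± 0.13) higher. Its shift down had a camera adjusted p of 0.0365 (adjusted p = 0.431 with an estimated correlation) and of 0.0889 without KO replicate 1, 0.134 on ranks and 0.0938 with dim genes left out. The count of lower genes was 3 when either KO array was left out, and Agpat2 had an adjusted p of 0.0505 without KO replicate 2.

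Sterol genes did not move together. Of 20 genes of cholesterol synthesis and uptake, 1 was higher, 2 lower and 17 not past the test, counts that were the same when adjusted over the list alone. The synthase gene Hmgcs1 differed by -0.55 ± 0.10, Fdps by -0.40 ± 0.10 and Hsd17b7 by 0.54 ± 0.13. Hmgcs1 passed without WT replicate 2 and with no other array left out, and Fdps and Hsd17b7 with none. The median (0.08), the mean (-0.01) and camera (down, adjusted p = 0.849) did not share a sign. Of 16 genes of fatty acid synthesis and desaturation, the desaturase gene Fads1 was higher (2.25 ± 0.19), Elovl5 (-0.88 ± 0.11) and Scd2 (-0.67 ± 0.11) were lower, and 13 were not past the test (1 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.465). Scd2 was not past the test without KO replicate 1 (adjusted p = 0.0522) or without KO replicate 2 (adjusted p = 0.0657). Of 15 genes of cholesterol efflux and LXR response, 4 were higher and 6 lower (5 and 7 when adjusted over the list alone). The apolipoprotein genes Apoe (3.91 ± 0.25) and Apoc2 (2.20 ± 0.19) were higher, and Nr1h3, which encodes the sterol receptor LXRα (-2.11 ± 0.17), and Scarb1 (-1.37 ± 0.12) were lower. The list did not shift (camera adjusted p = 0.428, down), with a median of -0.16 and a mean of 0.01, and 2 of its genes were higher without KO replicate 1.

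**Figure D2:**
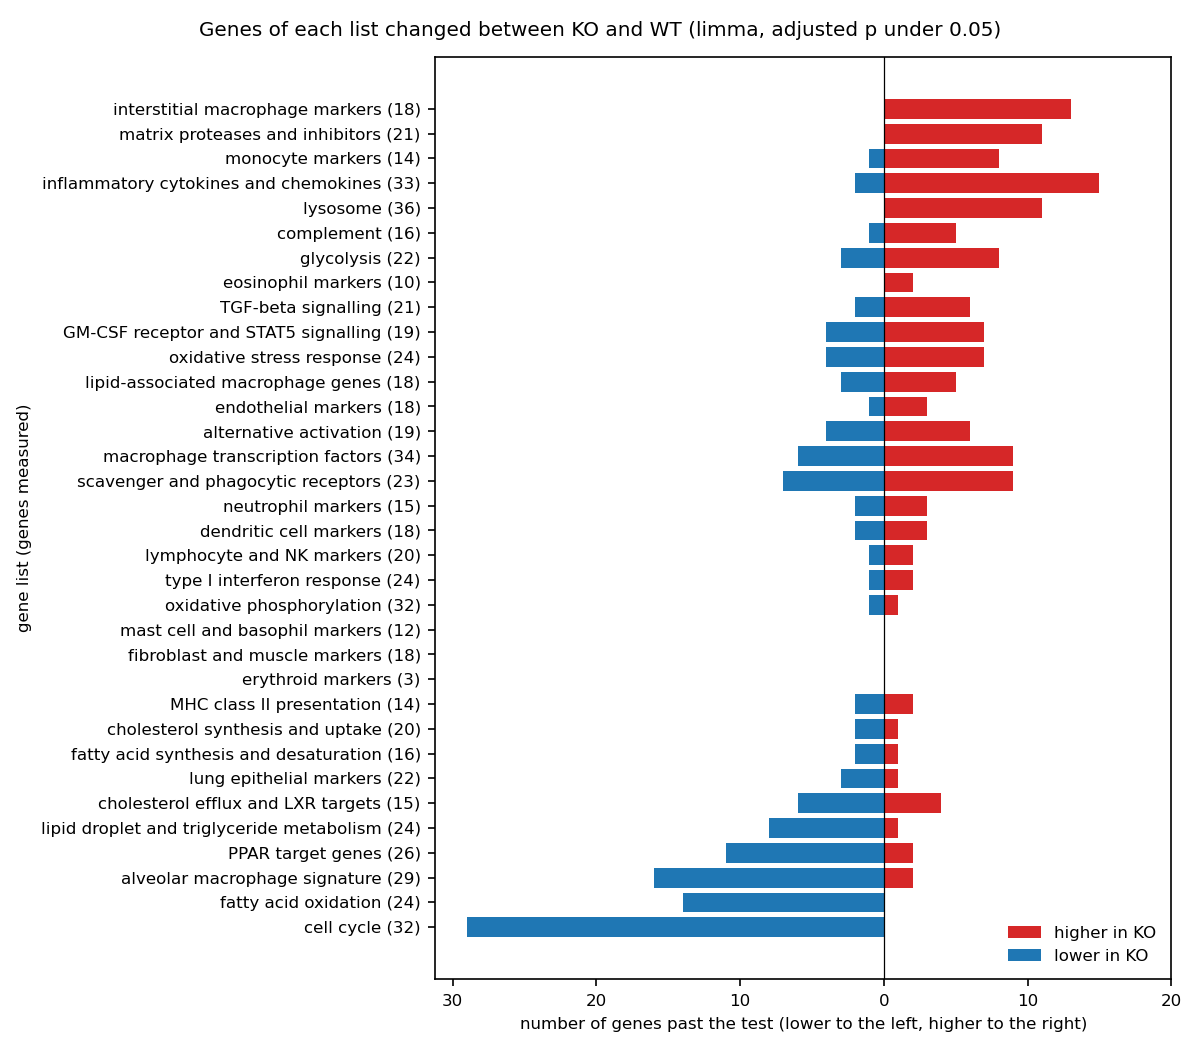
Number of genes of each list that were higher (right, red) or lower (left, blue) in KO by limma with an adjusted p under 0.05; the number of measured genes stands behind each list's name. Cell cycle had 29 of 32 genes lower and 0 higher, and interstitial macrophage markers had 13 of 18 genes higher and 0 lower.

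Genes of proliferation were lower in KO almost throughout. Of 32 measured cell cycle genes, 29 were lower, 0 higher and 3 not past the test, and all 32 were lower when adjusted over the list alone, with a median of -1.37. The mitotic kinesin gene Kif23 fell by 2.45 ± 0.15 from 7.35 ± 0.03 (SD, n = 2) to 4.91 ± 0.28 (SD, n = 2), Mcm5 and Mcm7, which encode parts of the replicative helicase, by 1.79 ± 0.13 and 1.48 ± 0.11, and the cyclin gene Ccnb2 by 1.70 ± 0.13. The list shifted down (camera adjusted p = 6.67e-23; adjusted p = 0.423 with an estimated correlation), and between 27 and 28 genes were lower when any 1 array was left out.

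More cytokine and chemokine genes were higher than lower in KO. Of 33 genes, 15 were higher, 2 lower and 16 not past the test (19 higher and 2 lower when adjusted over the list alone), with a median of 0.64. The largest of the named members were the prostaglandin synthase gene Ptgs2 (4.52 ± 0.30), the macrophage growth factor gene Csf1 (4.23 ± 0.18), Cxcl16 (11.3-fold) and Cxcl10 (2.34 ± 0.16), while Cxcl9 (-0.64 ± 0.12) and Ccl22 (-1.02 ± 0.22) were lower. The list shifted up (camera adjusted p = 1.75e-07; adjusted p = 0.423 with an estimated correlation), and 9 genes were higher without KO replicate 1. Of its lower genes 0 passed without KO replicate 2 and 1 without KO replicate 1 or without WT replicate 1. Of 18 genes of cell stress and dissociation, some of them also induced by cytokines, 5 were higher and 0 lower (5 and 0 when adjusted over the list alone), led by Socs3 (3.43 ± 0.15), Ier3 (1.77 ± 0.17) and Egr1 (1.26 ± 0.15). In that list 3 were higher without KO replicate 1 and 3 without WT replicate 1, and 1 was lower without WT replicate 2. Of 24 genes of the type I interferon response, 2 were higher, 1 lower and 21 not past the test, counts that were the same when adjusted over the list alone. Usp18 differed by 1.02 ± 0.17, Bst2 by 0.63 ± 0.11 and Zbp1 by -0.52 ± 0.12 (camera adjusted p = 0.28 for the list). Neither Bst2 (adjusted p = 0.0779) nor Zbp1 (adjusted p = 0.166) passed without KO replicate 1, nor without WT replicate 1, and Zbp1 also failed without KO replicate 2.

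Of 21 genes of matrix proteases and their inhibitors, 11 were higher, 0 lower and 10 not past the test (12 and 0 when adjusted over the list alone), with a median of 0.44. Besides Mmp12, the metalloprotease genes Adam8 (3.46 ± 0.37), Mmp2 (3.22 ± 0.16) and Mmp14 (3.10 ± 0.13) were higher (camera adjusted p = 3.00e-07 for the list; adjusted p = 0.431 with an estimated correlation), and 7 genes were higher without KO replicate 1. Of 36 lysosome genes, 11 were higher, 0 lower and 25 not past the test (11 and 0 when adjusted over the list alone), with a smaller median of 0.15. Cd63 was higher by 2.14 ± 0.16, Ctsk by 0.83 ± 0.11, Ctsl by 0.76 ± 0.11 and the galactosidase gene Glb1 by 0.72 ± 0.10, and Ctsl had an adjusted p of 0.0528 without KO replicate 1. The lysosome list shifted up (camera adjusted p = 1.96e-04; adjusted p = 0.423 with an estimated correlation). Its count of higher genes was 3 without KO replicate 1, 5 without KO replicate 2, 6 without WT replicate 2, 7 without WT replicate 1 and 18 with an intensity trend in limma.

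Scavenger and phagocytic receptors went both ways. Of 23 genes, 9 were higher and 7 lower (9 and 10 when adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.477). The collectin receptor gene Colec12 (3.19 ± 0.25) and Timd4, which encodes a receptor for phosphatidylserine (2.21 ± 0.10), were higher, while Fcgr4 (-2.66 ± 0.18) and Scarb1 were lower. The count of lower genes was 3 without KO replicate 1, 2 without KO replicate 2 and 4 without WT replicate 1. Of 18 genes of lipid-associated macrophages, Trem2 (2.57 ± 0.09), Apoe, Cd63 and Gpnmb (1.35 ± 0.12) led 5 higher genes, and Lpl (-1.22 ± 0.12), Plin2 (-0.65 ± 0.10) and Axl (-0.42 ± 0.09) were lower, with 1 lower when either KO array was left out (5 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.235).

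Markers of other lung macrophages and of monocytes were higher in KO. Of 18 interstitial macrophage markers, 13 were higher, 0 lower and 5 not past the test (15 and 0 when adjusted over the list alone), with a median of 0.82. They included C1qb, Pla2g2d, C1qc (4.84 ± 0.13) and C1qa (3.77 ± 0.12), which measured 2.41 ± 0.02 (C1qc) and 3.37 ± 0.13 (C1qa) in WT and 7.25 ± 0.24 (C1qc) and 7.14 ± 0.12 (C1qa) in KO (SD, n = 2). The shift up had a camera adjusted p of 4.13e-12 (adjusted p = 0.423 with an estimated correlation), and 8 genes were higher without KO replicate 1. Of 14 monocyte markers, 8 were higher and 1 lower (8 and 1 when adjusted over the list alone), with a median of 0.72. The fractalkine receptor gene Cx3cr1 (2.91 ± 0.16), Clec4e (1.48 ± 0.12) and Ace (0.96 ± 0.17) were higher and Treml4 was lower (-2.39 ± 0.31). Camera gave an adjusted p of 2.43e-04 for the list (adjusted p = 0.423 with an estimated correlation), and Ace was not past the test when either KO array was left out. Its count of higher genes was 5 without WT replicate 1, 4 without KO replicate 1 and 3 without KO replicate 2. Both lists moved with the gate, since the KO cells were sorted as CD11b-high and the WT cells as CD11b-low.

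**Figure D3:**
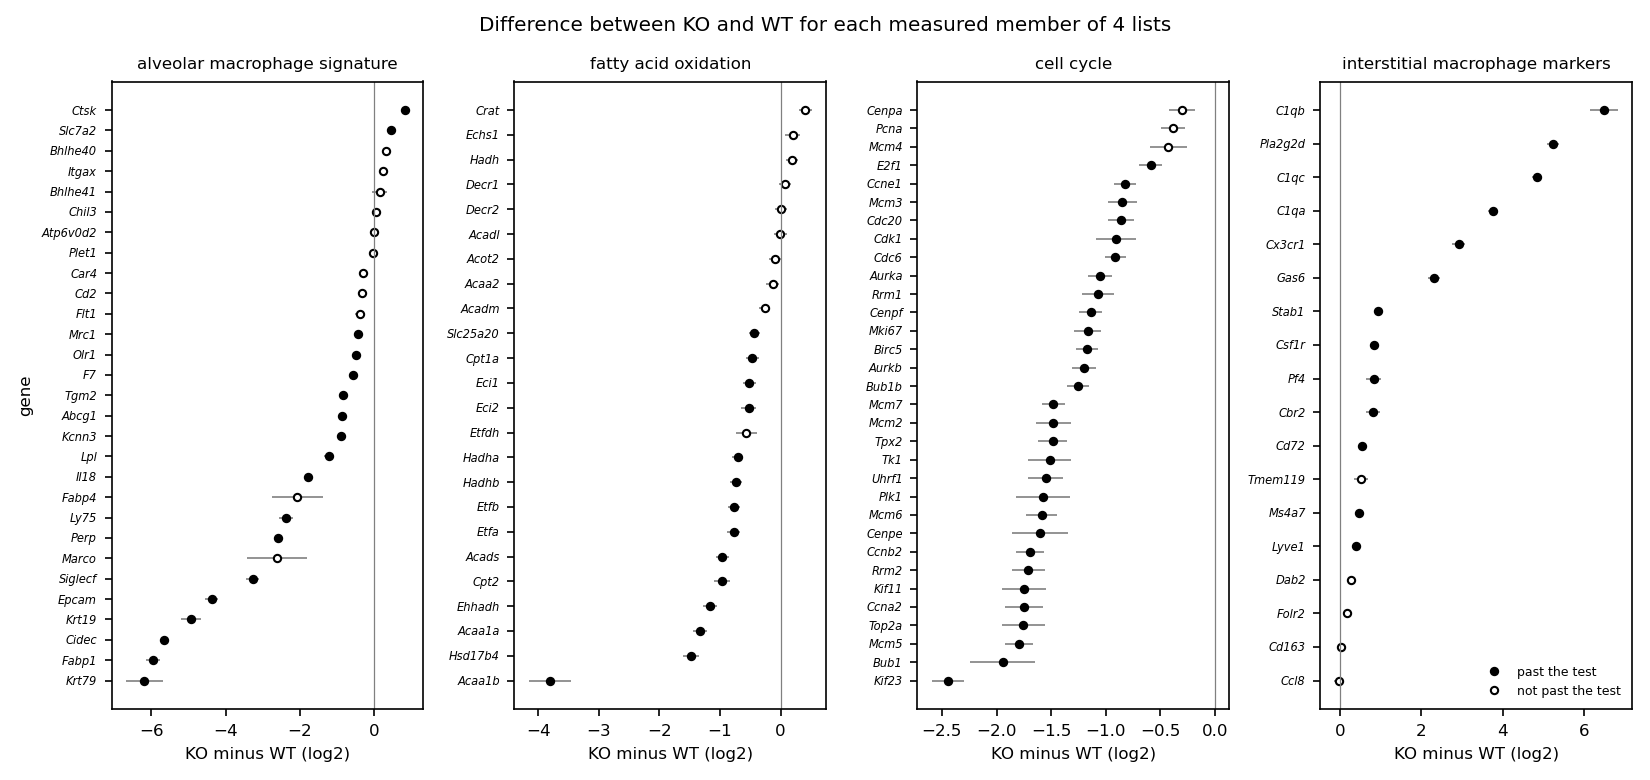
Difference between KO and WT (log2, KO minus WT) of each measured member of 4 lists, as points with the standard error of the limma model; filled points are past the test at an adjusted p under 0.05 and open points are not. All 32 cell cycle points lie below 0, while the alveolar macrophage signature runs from -6.19 for Krt79 to 0.83 for Ctsk.

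Of 18 dendritic cell markers, 3 were higher and 2 lower (3 and 3 when adjusted over the list alone; camera adjusted p = 0.485), led by Cd209a (2.04 ± 0.19) and Cd24a (1.17 ± 0.16), and 0 were lower without KO replicate 1 or without WT replicate 1. Of 10 eosinophil markers, Rnase2a and Cd24a were higher and 0 lower (3 and 0 when adjusted over the list alone; camera adjusted p = 0.0704, 0.0301 with dim genes left out and 0.0227 without KO replicate 2). Of 15 neutrophil markers, 3 were higher and 2 lower (4 and 2 when adjusted over the list alone; camera adjusted p = 0.137, and 0.0221 without KO replicate 2), with Ceacam10 (2.52 ± 0.15) and S100a8 (1.92 ± 0.18) higher and Wfdc21 (-1.58 ± 0.10) and Csf3r (-1.54 ± 0.18) lower. Of 20 lymphocyte and natural killer cell markers, Il7r (a 16-fold difference) and Cd4 (0.42 ± 0.10) were higher and Prf1 (-0.73 ± 0.16) lower (2 and 1 when adjusted over the list alone; camera adjusted p = 0.231). Cd4 passed with no array left out, and Prf1 only without WT replicate 2. Of 22 lung epithelial markers, Hopx was higher (2.66 ± 0.19) and Ager (-1.32 ± 0.12), Cldn18 (-1.07 ± 0.15) and Krt18 (-0.57 ± 0.12) were lower (1 and 4 when adjusted over the list alone; camera adjusted p = 0.838). Krt18 passed without KO replicate 2 and with no other array left out, and Cldn18 had an adjusted p of 0.0541 without KO replicate 2. Of 18 endothelial markers, Epas1 (2.29 ± 0.20), Cav1 (1.72 ± 0.10) and Vwf (1.17 ± 0.10) were higher and Calcrl lower (-0.87 ± 0.13; 3 and 1 when adjusted over the list alone), Calcrl with an adjusted p of 0.0595 without KO replicate 2. The endothelial median was -0.11, its mean 0.13, and camera gave down with an adjusted p of 0.849. In each of the fibroblast and muscle (18 genes), mast cell and basophil (12 genes) and erythroid lists (3 genes), 0 genes passed limma's test over all genes or adjusted over the list alone, with camera adjusted p-values of 0.849, 0.875 and 0.648. Their smallest p-values belonged to Gsn (-0.34 ± 0.10) and Acta2 (0.37 ± 0.12), to Hdc (0.66 ± 0.29) and Gata2 (0.17 ± 0.10), and to Alas2 (0.22 ± 0.11) and Slc4a1 (-0.06 ± 0.11), while Hdc passed without KO replicate 2 (adjusted p = 0.0108). Without KO replicate 1, 1 eosinophil marker was lower, and without WT replicate 1, 1 fibroblast marker was lower and 2 epithelial markers were higher.

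The test behind these calls rests on 2 pools per group, so a gene that differs between pools of 1 genotype can miss it by a wide margin. WT replicate 2 lay closer to the KO arrays than WT replicate 1 on the first principal component (-33.2 against -43.4, with KO at 39.3 and 37.3). The median difference between WT replicate 2 and WT replicate 1 was -0.05 for the alveolar macrophage signature, -0.16 for PPAR targets, -0.06 for cell cycle, 0.01 for interstitial macrophage markers and 0.21 for monocyte markers.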

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

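The tests of exchanged labels, of interstitial macrophages or monocytes inside the gate, of KO-type cells in WT replicate 2 and of stress were chosen after the result was seen, and those of sex and of eosinophils or neutrophils before. Among probe sets that carry no single gene name and entered no comparison by gene, 183 were higher in KO than in WT by limma, of which 63 carry several gene names and 120 carry none, and 70 and 124 of each kind were lower. Differences reached 5.55 among those without a name and 4.45 among those with several. The cause was not tested.

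The number of genes changed between KO and WT was large while Pparg itself differed by -0.06 ± 0.10 (SE, limma adjusted p = 0.79). A difference in the sex of the pooled mice is argued against by Xist and the Y-linked genes, whose largest absolute difference was 0.083, with Xist at 1.57 in both groups. A WT and a KO array with exchanged labels is argued against by the correlations, since the lowest within a label lay 0.0154 above the highest between labels, and an exchange of all the labels by Itgam, at 2.98 in WT and 8.74 in KO, the order of the CD11b gates. The genotype stays among the open explanations as a hypothesis that these arrays did not test, because Pparg does not show the deletion and the gate differs with the genotype.

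Markers of interstitial macrophages and monocytes were higher in KO. Interstitial macrophages or monocytes inside the CD11b-high gate may be a source. How many of them the gate on Siglec-F, CD11c and autofluorescence removed was not measured here. Siglecf itself was lower in KO by -3.27 ± 0.17 (SE). The median difference of Cd74, H2-Aa, H2-Ab1 and H2-Eb1, MHC class II genes abundant in interstitial macrophages, was -0.772. This leaves that source open, since monocytes carry little MHC class II and a fall within alveolar macrophages would mask a rise. Eosinophils or neutrophils stay open too. The largest difference among S100a9, Prg2 and Epx was 0.567, that of S100a9, while Prg2 differed by -0.08 and Epx by 0.08. S100a9 read 2.457 in WT and 3.024 in KO, both below the array median of 3.137. Prg2 (1.937 in WT, 1.855 in KO) and Epx (1.872 in WT, 1.953 in KO) lay near the bottom of the scale. Of 10 eosinophil markers 2 were higher and 0 lower, and of 15 neutrophil markers 3 were higher and 2 lower. A change within the alveolar macrophages of KO mice is the untested biological explanation, and it cannot be told apart from other cells because the gate differs between the groups by design.

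WT replicate 2 lay towards the KO arrays, as the difference between the WT arrays correlated with that between KO and WT across genes, which are not independent replicates (r = 0.294, against -0.066 for the difference between the KO arrays). Of the genes higher in KO by at least 1 on the log2 scale, 74% were higher in WT replicate 2 than in WT replicate 1, and of those lower in KO 73.6% were lower there. Cells of the KO type in the pool of WT replicate 2, as the only source of this lean, are argued against. The genes higher in KO by at least 3 would need a median share of 1.22% (quartiles 0.07 to 3.11, 87 genes). The genes lower by at least 3 would need a share of 28.2% (quartiles 15.4 to 47.7, 29 genes). A small share of such cells beside another source is not excluded. Stress during dissociation is argued against by the stress list, whose median difference between WT replicate 2 and WT replicate 1 was -0.188 (SD 0.283 over genes) where the genes higher in KO had 0.179. A difference between the mice of the WT pools was not tested and stays open.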

How the results depend on the processing

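No test reported in this part was chosen after the result was seen except those for Marco and Fabp4, although the lists treated as leading results were picked after their counts were seen. Quantile normalization again and a shift to 1 median changed no call and no count, since the arrays already shared 1 distribution, and array weights came out at 1 for each array, which says nothing about stability. With each array left out, genes higher in KO numbered 726 to 1227 and lower 647 to 1057, against 1391 and 1289 with all arrays. Treat against 0.5 called 498 higher and 336 lower, and the ordinary test without moderation called 0 and 0, also 0 and 0 at 1 or more on the log2 scale, with 3635 genes at an unadjusted p under 0.05, of which 2149 were among limma's 2680. For that test 3 genes whose arrays had no spread after rounding were left out. PPAR target genes lower ran from 7 to 11, lysosome genes higher from 3 to 7 (18 with an intensity trend), inflammatory genes higher from 9 to 14, matrix protease genes higher from 7 to 8, monocyte markers higher from 3 to 8 and interstitial macrophage markers higher from 8 to 11 over the arrays left out. Each fit with an array left out had 1 residual degree of freedom. With an estimated correlation, camera's adjusted p was 0.423 for the alveolar macrophage signature, fatty acid oxidation, lysosome, inflammatory, cell cycle, monocyte and interstitial macrophage lists, 0.435 for PPAR targets and 0.431 for matrix proteases, and 12 of 12 list calls were lost, with 2 residual degrees of freedom behind each correlation. fry gave 0.0186 to 0.0423 for these lists in one direction. The intensity trend called 3259 genes (2595 shared with the 2680), robust moderation 2690 (2670 shared), the filter on dim genes 2858 (2613 shared) and the mean of probe sets 2709 (2634 shared). With the trend, counts also moved by over 1.5 times to 4 higher in the alveolar macrophage signature, 3 higher for lipid droplets, 5 lower each for lipid-associated macrophages, glycolysis, MHC class II and oxidative phosphorylation, 2 higher for oxidative phosphorylation, 2 lower each for complement and lysosome, 2 higher for the sort gate, 1 higher for fatty acid oxidation and 1 higher for lymphocytes. No result was reversed under any of these alternatives. Neither Marco nor Fabp4 was past the test with all arrays. With any array left out their differences kept a negative sign, from -1.23 to -4.01 for Marco and from -0.89 to -3.25 for Fabp4. A fit with a single WT array cannot see the spread between the WT arrays. Signal near the bottom of the scale limits what a dim gene can show.

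The groups share replicate numbers in the labels. With the replicate block limma called 2477 genes, 2346 of them among the 2680 called without it, and 1309 were higher and 1168 lower. Of the named genes, Fdps, Zbp1, Prf1 and Cd4 passed only without the block, and the glycolysis list had a camera adjusted p of 0.0492 with it. The lower scavenger and phagocytic receptor genes numbered 3 with the block against 7 without it. Same-numbered arrays deviated from their group means with a correlation of -0.017 across genes. No broad shift common to them was seen. This cannot exclude a shared batch that acted on few genes or differently in each group.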

Other observations

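No test in this part was chosen after the result was seen. Genes of glucose use were higher in KO more often than lower. Of 22 glycolysis genes, 8 were higher and 3 lower (9 and 4 when adjusted over the list alone), with Ldhb (3.45 ± 0.16 SE), the glucose transporter gene Slc2a1 (1.88 ± 0.14), the hexokinase gene Hk2 (1.38 ± 0.10) and Pgam1 (0.87 ± 0.10) higher, and Pdk1 (-1.29), Pfkfb4 (-0.71) and Pfkp (-0.44) lower. The list's shift had a camera adjusted p of 0.0578, with 0.0328 without WT replicate 1, and 4 genes were higher and 1 lower without KO replicate 1. Of 32 genes of oxidative phosphorylation, 1 was higher and 1 lower, namely Ndufb8 (0.48 ± 0.10) and Ndufa4 (-0.60 ± 0.12), and Ndufb8 passed with no array left out and Ndufa4 only without WT replicate 1. The counts were the same when adjusted over the list alone (camera adjusted p = 0.178, and 0.0256 without KO replicate 1). With an intensity trend in limma 2 were higher and 5 lower. Of 24 genes of the oxidative stress response, 7 were higher and 4 lower (7 and 5 when adjusted over the list alone; camera adjusted p = 0.534), with the glutathione peroxidase gene Gpx3 (4.71 ± 0.30), the cystine transporter gene Slc7a11 (2.23 ± 0.23) and Gstm1 (0.65 ± 0.10) higher and Taldo1 (0.499 of the WT level), Hmox1 (-0.59), Gsr (-0.52) and Mgst1 (-0.48) lower. Between 3 and 4 of these genes were higher and between 1 and 2 lower when any 1 array was left out, and Gstm1 had an adjusted p of 0.0537 without KO replicate 2. Of members named here beyond the 4 with the smallest p of a list, all were chosen after their values were seen.

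Immune signalling genes moved in both directions. Of 16 complement genes, 5 were higher and 1 lower (5 and 3 when adjusted over the list alone), namely C3ar1, the 3 C1q genes that are also interstitial macrophage markers, and C2 (1.59) higher and the anaphylatoxin receptor gene C5ar1 (-1.19) lower, with 2 lower without WT replicate 2. Camera gave an adjusted p of 0.0547, with 0.0375 when dim genes were left out, 0.475 on ranks, 0.0241 without WT replicate 2 and 0.0235 without KO replicate 2. Of 14 genes of MHC class II presentation, the costimulatory genes Cd86 (1.28 ± 0.30) and Cd80 (0.50 ± 0.11) were higher and Cd74 (-0.84 ± 0.17) and H2-Ab1 (-0.89 ± 0.19) lower (2 and 3 when adjusted over the list alone; camera adjusted p = 0.527). None of these 4 calls held without KO replicate 1, Cd86 alone passed without WT replicate 1, and Cd80 and Cd86 did not pass without KO replicate 2. With an intensity trend 5 genes of the list were lower. Of 19 genes of alternative activation, 6 were higher and 4 lower (9 and 5 when adjusted over the list alone), with Retnla (2.99 ± 0.28), Irf4 (2.91 ± 0.23) and Mgl2 (1.68 ± 0.11) higher and Tgm2 (-0.85 ± 0.10), Pdcd1lg2 (-1.08), Ccl22 and Mrc1 (-0.44) lower, and 2 were lower when either KO array was left out. Its shift up had a camera adjusted p of 0.0368 (adjusted p = 0.431 with an estimated correlation) and of 0.0735 without WT replicate 1 and 0.0506 without KO replicate 1. It was 0.0707 on ranks and 0.0938 with dim genes left out, and fry gave 0.0592 in one direction. Of 19 genes of GM-CSF receptor and STAT5 signalling, 7 were higher and 4 lower (9 and 4 when adjusted over the list alone), with the feedback inhibitor gene Socs3 (3.43), Ccnd1 (1.27 ± 0.13) and Myc (1.02 ± 0.11) higher and Ccnd2 (-2.00 ± 0.17), Stat5a (-0.88), Stat5b and Spi1 (-0.51) lower. Its camera adjusted p was 0.0365 (adjusted p = 0.435 with an estimated correlation; 0.0633 without WT replicate 1, 0.0545 without KO replicate 2, 0.0687 on ranks and 0.0689 with dim genes left out), and 3 genes were higher without KO replicate 1 and 4 without KO replicate 2. Of its lower genes 2 passed when WT replicate 1 or either KO array was left out. Of 34 macrophage transcription factors, 9 were higher and 6 lower (14 and 6 when adjusted over the list alone; camera adjusted p = 0.0578, and 0.0247 without WT replicate 1 or 0.0437 without KO replicate 1), led by Irf4, Id2 (1.24 ± 0.10), Nr1h3 and Zeb1 (-1.19 ± 0.10), with 3 lower when WT replicate 1 or either KO array was left out. Of 21 genes of TGF-beta signalling, 6 were higher and 2 lower (7 and 2 when adjusted over the list alone; camera adjusted p = 0.189), with the co-receptor gene Eng (2.17 ± 0.27) and Smad6 (0.78 ± 0.10) higher and Acvrl1 (-0.62 ± 0.11) and Tgfb2 (-1.01) lower, and 2 genes higher when either KO array was left out. Acvrl1 had an adjusted p of 0.0762 without KO replicate 2, where 0 genes of the list were lower, and 1 was lower without KO replicate 1. Of 4 measured sex-linked genes 0 passed limma's test, over all genes or adjusted over the list alone.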
